A study of Mus musculus with 4 samples.

How the data were processed

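Total RNA of 4 sorted islet cell populations was sequenced, with 1 library per population. Per the labels' protocols, the cells came from male MIP-GFP C57BL/6 mice aged 6 to 8 weeks, with 3 mice per group, injected intraperitoneally with 200 mg/kg of streptozotocin (STZ) in citrate buffer or with vehicle. RNA was isolated on Norgen columns, and stranded total RNA libraries were made with an Illumina TruSeq kit after removal of ribosomal RNA with Ribo-Zero Gold. Per the submitters' processing notes, reads were handled with TopHat2, SAMtools and Cuffdiff on the GRCm38 (mm10) genome. Versions, the annotation release and the library normalization setting are not given in the sources used here.

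The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), per the file headers, in a Cuffdiff gene table with 1 value, 2 interval bounds and a status per gene and library. The table has 39170 rows for 38923 distinct symbols. The status was OK in all 4 libraries for 38733 rows, and 432 rows had a status of LOWDATA, 3 of HIDATA and 2 of FAIL in some library. The separate tables of the 4 samples hold the same FPKM: of 156680 values compared, 0 differed. Genes were annotated by Ensembl ID with GENCODE release M21 on GRCm38, which matched 37607 rows, 21226 of them protein-coding. Positions are from that annotation.

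The number of reads per library is unknown and was not recovered from the values: among 884 genes below 0.5 FPKM, the fullest bin of 0.05 on the log2 scale held 20. The level of the deposited intervals is not stated. Their median half-width was 82.1%, 80.3%, 83.4% and 79.0% of the FPKM in the Glut2H control, Glut2L control, Glut2H STZ and Glut2L STZ libraries. Some values lay outside their own interval (124, 169, 107 and 149), so the bounds were used in an alternative alone.

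Libraries were grouped by gate and treatment as labelled, and 4 comparisons were made: Glut2L against Glut2H in control and in STZ mice, and STZ against control within each gate, followed by the difference of the STZ effects of the gates. Each took log2 of FPKM plus 1 as deposited, over genes with an FPKM of at least 1 in either library and a status of OK in both, and counted genes that differed at least 2-fold. With 1 library per group no test was run and no p-value is given. For each of 24 gene lists with at least 3 measured members, the median log2 value was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean log2 level. The lists hold 377 symbols, of which 373 are in the table, and 120 medians were looked for. Random lists treat genes as independent, so percentiles describe these libraries and are no test of a treatment or gate.

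The lists covered beta cell identity, hormone granules, alpha cells, other islet endocrine cells, acinar, duct, endothelial, immune, stromal, red blood and neural cells, pancreatic progenitors, dedifferentiation and disallowed genes. They also covered the cell cycle, G1 cyclins with CDK inhibitors, p53 targets, the unfolded protein response, oxidative stress, glycolysis, the respiratory chain, interferon, immediate early with heat shock genes, and the Notch pathway.

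Genes were named by a rule with 3 parts, fixed with the lists, comparisons and most alternatives before the data were examined. It named Slc2a2, Ins1 and Ins2 in every library. It named the 10 highest and 10 lowest log2 values per comparison (5 and 5 for the difference) among genes with at least 5 FPKM in the higher library and a status of OK, without loci under 300 bp, rows of several genes, and predicted genes and small RNAs as far as fixed patterns of their symbols caught them. Last, it named the 2 highest and 2 lowest members of each list described, with at least 5 FPKM, and each member of the progenitor, cell cycle and p53 lists that differed at least 2-fold. The patterns missed many small RNAs with symbols of another form, so the second part mostly named microRNA and other noncoding genes, with at most 3 protein-coding genes among any 10. A ranking of protein-coding genes without selenoproteins, chosen after the values were seen, is therefore given in its place, and some further list members and cell type markers were also named after their values were seen. A few genes that the rule named are not reported here.

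The alternatives were a pseudocount of 0.1 or 5, no filter on low values or a filter of 5 FPKM, named genes alone, non-overlapping intervals, the per-sample tables, and 3 scalings. These set the median of all log2 ratios to 0, rescaled FPKM to an equal sum over all rows, or did so without the 20 highest rows, mitochondrial genes and loci under 300 bp. Protein-coding genes without selenoproteins were added after the data were seen. The procedure was tested on simulated data: with 4-fold changes placed in 100 genes in each direction among 15602, all were recovered, 0 unchanged genes were called, and 13 of 200 lists of unchanged genes fell outside the central 95% of random lists. This checks the code and says nothing of the spread between libraries. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.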

Results

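RNA was sequenced from sorted islet cells of male MIP-GFP mice, which make green fluorescent protein under the mouse insulin 1 promoter. Insulin-positive cells were sorted on Glut2, the glucose transporter encoded by Slc2a2, into a high (Glut2H) and a low (Glut2L) gate. Each gate was sorted from vehicle-treated control mice and from mice given 200 mg/kg of streptozotocin (STZ), which were diabetic 4 days after injection. STZ is a DNA-alkylating toxin that enters beta cells through Glut2. The 4 groups (Glut2H control, Glut2L control, Glut2H STZ and Glut2L STZ) hold 1 library each. There is no replicate check: no spread between libraries of a group can be had, no difference was tested, and every comparison describes these 4 libraries. The labels give 3 mice per group, and whether RNA of several mice was pooled is not given in the sources used here. Values are FPKM, in the order Glut2H control, Glut2L control, Glut2H STZ and Glut2L STZ, and the number of reads behind them is unknown. The deposited FPKM summed to 2935080, 1654280, 3428740 and 1562040, and 14425, 14117, 13714 and 14005 rows of the table reached 1 FPKM. A single short predicted gene, Gm20594, took 61.0%, 3.86%, 68.5% and 4.15% of each sum. Log2 values compare FPKM plus 1, and percentiles place a list's median among 10000 random gene lists matched on level, as a description of these libraries.

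The Slc2a2 transcript went against the gate labels. Its FPKM was 8.74, 41.0, 10.8 and 33.7 (ENSMUSG00000027690, GRCm38 chromosome 3, 28697903 to 28731359), so it was higher in the library labelled Glut2L by 2.11 on the log2 scale in control mice and by 1.55 after STZ. The insulin genes moved the same way. Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) stood at 57345, 294540.0, 52596 and 175841 FPKM and Ins1 (ENSMUSG00000035804, chromosome 19, 52264297 to 52265476) at 8955, 30842, 8471 and 20766. Together they made up 2.26%, 19.7%, 1.78% and 12.6% of the summed FPKM. These shares overstate the gap between the gates, because Gm20594 took 61.0% and 68.5% of the Glut2H control and STZ sums. In the Glut2L libraries it took 3.86% and 4.15%. The gates are therefore named by their labels throughout, and each direction drawn between them is a direction between libraries so labelled.

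**Figure D1:**
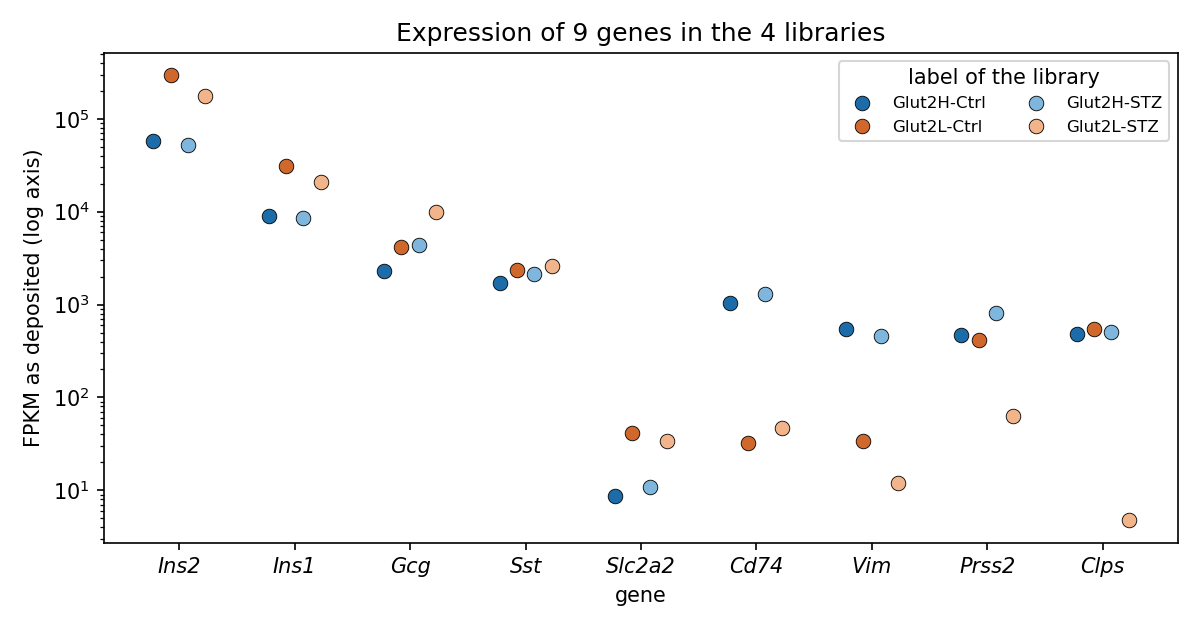
FPKM on a log axis of Ins2, Ins1, Gcg, Sst, Slc2a2, Cd74, Vim, Prss2 and Clps, with 1 point for each of the 4 libraries. Slc2a2 lay at 8.74, 41.0, 10.8 and 33.7 and Cd74 at 1027, 32.4, 1305 and 46.9 in the order given in the text, and Clps was at 4.75 in the library labelled Glut2L after STZ against 540.2 in its control.

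The comparison of the gates asks how insulin-positive cells with little Glut2, described by the submitters as rich in multipotent pancreatic progenitors, differ from those with much of it. In both control and STZ mice the library labelled Glut2L held more RNA of beta cell and secretory granule genes, and the library labelled Glut2H held more RNA of immune, endothelial and stromal genes. Of 22 beta cell identity genes, 18 were at least 2-fold higher in the library labelled Glut2L in control mice (median 1.59, percentile 100) and 19 after STZ (median 1.41, percentile 100), and none was at least 2-fold lower in either pair. Glp1r, the receptor of the incretin GLP-1, stood at 19.998, 93.9, 22.2 and 82.4 FPKM, the transcription factor gene Nkx2-2 at 9.69, 46.0, 13.2 and 56.0 and Kcnj11, a subunit of the ATP-sensitive potassium channel, at 7.16, 21.1, 5.59 and 29.2. The smallest control differences of the list were in Trpm5, at 4.06, 6.08, 4.71 and 10.6, and Neurod1, at 34.2, 58.0, 29.1 and 68.3. After STZ they were in G6pc2, at 98.1, 420.0, 136 and 247, and Foxa2, at 6.23, 12.8, 12.3 and 24.2.

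Genes of hormone granules and exocytosis were at least 2-fold higher in the library labelled Glut2L for 18 of 22 in control mice (median 1.47, percentile 100) and 18 of 22 after STZ (median 1.55, percentile 100). Scg5, a chaperone of prohormone convertase 2, stood at 201, 924, 244 and 799.9 FPKM, Chga, which encodes chromogranin A, at 1389, 5885, 1146 and 4494, and Vgf at 58.1, 206, 49.98 and 225. The unfolded protein and endoplasmic reticulum stress list followed: 16 of 20 genes were at least 2-fold higher there in control mice (median 1.42, percentile 100) and 9 of 20 after STZ (median 0.96, percentile 99.9). Sdf2l1 was at 14.8, 99.7, 12.6 and 55.2, the stress-inducible gene Creld2 at 20.5, 98.7, 15.1 and 62.5, and Hspa5, the main chaperone of the reticulum, at 519, 1987, 609 and 1385.

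Hormone genes of other islet cells were also measured. Gcg, which encodes glucagon (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650), stood at 2287, 4170.0, 4337 and 9893 FPKM, Sst at 1702, 2366, 2157 and 2604, Ppy at 2483, 4649, 2149 and 4962 and Pyy at 1424, 2532, 1305 and 2939. The alpha cell list had medians of 0.18 in the control pair and 0.84 in the STZ pair (percentiles 56.5 and 91.9), with Ttr at 9.11, 34.8, 5.82 and 59.6. The list of delta, PP and epsilon cells had medians of 0.87 and 0.69 (percentiles 92.9 and 87.3). Ghrl was listed at 0 in the Glut2H control library and at 5.37 in the library labelled Glut2L, and at 4.803 and 7.26 in the STZ libraries labelled Glut2H and Glut2L.

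Immune markers were the group with the lowest median of the lists measured in both pairs: 19 of 19 measured genes in control mice (median -4.55) and 18 of 19 after STZ (median -4.16) were at least 2-fold lower in the library labelled Glut2L. Cd74, the invariant chain of MHC class II, stood at 1027, 32.4, 1305 and 46.9 FPKM, Cd52 at 505, 5.11, 487 and 14.5, H2-Ab1 at 419, 6.04, 411 and 10.2 and Lyz2, the lysozyme of macrophages, at 332, 7.92, 250.4 and 6.39. C1qb was at 99.8, 2.49, 104 and 1.01, and the B cell gene Cd79a, which was not lower after STZ, at 8.83, 2.70, 1.61 and 2.46. Endothelial markers were at least 2-fold lower for 10 of 11 (median -2.96) and 11 of 11 (median -3.28), with Cdh5 at 24.0, 0.814, 10.1 and 0.142, Plvap at 60.3, 5.32, 26.5 and 0.795, Egfl7 at 66.5, 13.7, 116 and 3.73 and Pecam1 at 29.9, 2.96, 17.4 and 4.41. For stromal markers it was 14 of 14 (median -3.20) and 14 of 14 (median -3.80), with Vim at 546, 33.7, 455 and 11.97, Dcn at 92.8, 1.16, 45.1 and 2.24, Col1a1 at 51.5, 1.01, 54.6 and 0.619 and Acta2 at 6.40, 0.887, 22.4 and 0.707. The percentile was 0 for each of these 3 lists in both pairs. Hemoglobin transcripts were seen in the Glut2H control library alone, with Hba-a1 at 45.0 and Hbb-bs at 29.6, and both were listed at 0 in the other libraries. The red blood cell list had 4 measured genes in the control pair (median -3.96) and 0 in the STZ pair.

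Exocrine markers differed between the pairs. Acinar genes had a median of -0.30 in control mice, where 1 of 22 was at least 2-fold lower in the library labelled Glut2L, and this median turned to 0.58 when FPKM were rescaled to an equal sum over all rows. After STZ, 21 of 22 were at least 2-fold lower there (median -3.36, percentile 0). The trypsin gene Prss2 stood at 469, 417, 804 and 63.1 FPKM, the chymotrypsin gene Ctrb1 at 1083, 801, 1018 and 158 and the lipase gene Pnlip at 443, 329, 446 and 22.7, while Bhlha15, a transcription factor gene of secretory cells, was at 3.83, 6.94, 3.81 and 7.56. Duct markers were at least 2-fold higher in the library labelled Glut2L for 6 of 12 in control mice (median 1.02, percentile 99.5) and 7 of 13 after STZ (median 1.09, percentile 99.1). The members that were higher included keratins and an adhesion gene of epithelia: Krt7 at 11.5, 65.7, 9.82 and 36.0, Krt8 at 158, 449.8, 115 and 309.9 and Epcam at 38.2, 111, 35.4 and 125. Spp1, at 156, 63.1, 174 and 39.7, and Car2, at 13.5, 0.596, 12.2 and 0.225, were lower.

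At the deposited scale, pancreatic progenitor genes, the group the low gate is meant to enrich, were not raised together in the libraries labelled Glut2L. In control mice 0 of 9 measured genes were at least 2-fold higher there and 3 were at least 2-fold lower (median -0.30, percentile 12.6). That median turned to 0.34 when rescaled to an equal sum over all rows. The lower members were Aldh1b1 at 22.3, 0.470, 2.29 and 0.985 FPKM, the intermediate filament gene Nes at 28.4, 2.52, 25.2 and 3.70, and Procr at 101, 13.7, 155 and 10.7; Nes and Procr are also expressed by stromal and endothelial cells, whose markers were lower as well. After STZ, 2 of 12 were at least 2-fold higher, among them Lgr5 at 0.239, 0.978, 0.214 and 4.49, and 3 were lower, Procr, Nes and Ptf1a, the last at 0.198, 0, 2.45 and 0 (median 0.26, percentile 47.0). That median moved to 1.23 when rescaled to an equal sum over all rows, where the median of all genes was 1.08. Neurog3, the transcription factor gene of endocrine progenitors, stood at 1.76, 1.54, 0.433 and 1.45 and Sox9 at 0.844, 0.651, 1.26 and 0.229. Dedifferentiation genes had medians of -1.73 (percentile 0.04) and -0.05 (percentile 21.9), the STZ median turning to 0.52 when rescaled to an equal sum over all rows. Among them Ldha was at 83.6, 16.5, 80.6 and 10.2, Penk at 15.6, 0.994, 4.74 and 4.55, Gast at 10.2, 23.8, 0 and 1.06 and Npy at 16.5, 44.8, 13.8 and 27.5.

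Genes that mature beta cells keep silent, the disallowed list, were at least 2-fold lower in the library labelled Glut2L for 14 of 17 in control mice (median -1.96, percentile 0) and 13 of 17 after STZ (median -2.23, percentile 0), beside immune list medians of -4.55 and -4.16. Hk2 stood at 14.9, 0.119, 14.4 and 0.545 FPKM, Maf at 8.29, 0.193, 4.89 and 0.396 and the leukocyte gene Arhgdib at 39.6, 4.00, 37.1 and 0.333. Interferon and antigen presentation genes moved with the immune markers too: 15 of 20 (median -1.47) and 16 of 20 (median -2.16) were at least 2-fold lower, both at percentile 0. Ifit2 was at 98.3, 1.997, 49.7 and 1.21, B2m at 2254, 172, 1998 and 122 and H2-K1, which differed little, at 157, 145, 123 and 108.

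Apart from Pcna, at 47.1, 29.4, 44.1 and 38.7 FPKM, and Mcm7, at 8.84, 13.2, 13.9 and 15.6, cell cycle genes of S and G2/M stood below 10 FPKM in every library. In control mice 4 of 22 were at least 2-fold higher in the library labelled Glut2L (Ccnb1 at 1.24 and 7.14, Aurkb at 0.490 and 3.30, Ccna2 at 0.496 and 2.99 and Top2a at 2.44 and 6.13 FPKM in the Glut2H and Glut2L libraries) and 3 were lower (Mcm3 at 5.12 and 0.917, Bub1 at 2.10 and 0.139 and Birc5 at 1.92 and 0.187). The median was 0.07 (percentile 55.5) and turned to -0.08 with the median of all genes set to 0. After STZ 9 of 22 were higher (median 0.70, percentile 96.0): Ccnb2, listed at 0 in the Glut2H library, was at 3.43, Cdk1 at 0.156 and 2.88, Top2a at 2.04 and 8.50, Cdc20 at 0.898 and 4.97, Aurkb at 0.638 and 3.34, Ccnb1 at 0.234 and 2.20, Ube2c at 0.963 and 3.93, Rrm2 at 0.554 and 2.52 and Tpx2 at 3.01 and 7.27. Birc5, at 2.76 and 0.356, and Mcm3, at 3.76 and 0.934, were lower.

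In control mice p53 and DNA damage genes had a median of 0.09 (percentile 30.7), which turned to -0.06 with the median of all genes set to 0. Gadd45a, at 17.3 and 53.1 FPKM, was at least 2-fold higher in the library labelled Glut2L, and Plk2 (64.8 and 11.5), Eda2r (4.89 and 0.366), Pmaip1 (3.83 and 0.643) and Fas (4.70 and 1.31) were at least 2-fold lower. In the STZ pair the median was 0.65 (percentile 96.9), with 8 of 24 at least 2-fold higher and 0 lower. These were Fas at 0.137 and 8.63, Bbc3 at 2.25 and 13.5, Rrm2b at 3.47 and 14.3, Aen at 25.5 and 72.5, Trp53inp1 at 17.0 and 43.2, Gadd45a at 24.4 and 59.8, Ccng1 at 41.9 and 94.6 and Sesn2 at 14.2 and 32.1.

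**Figure D2:**
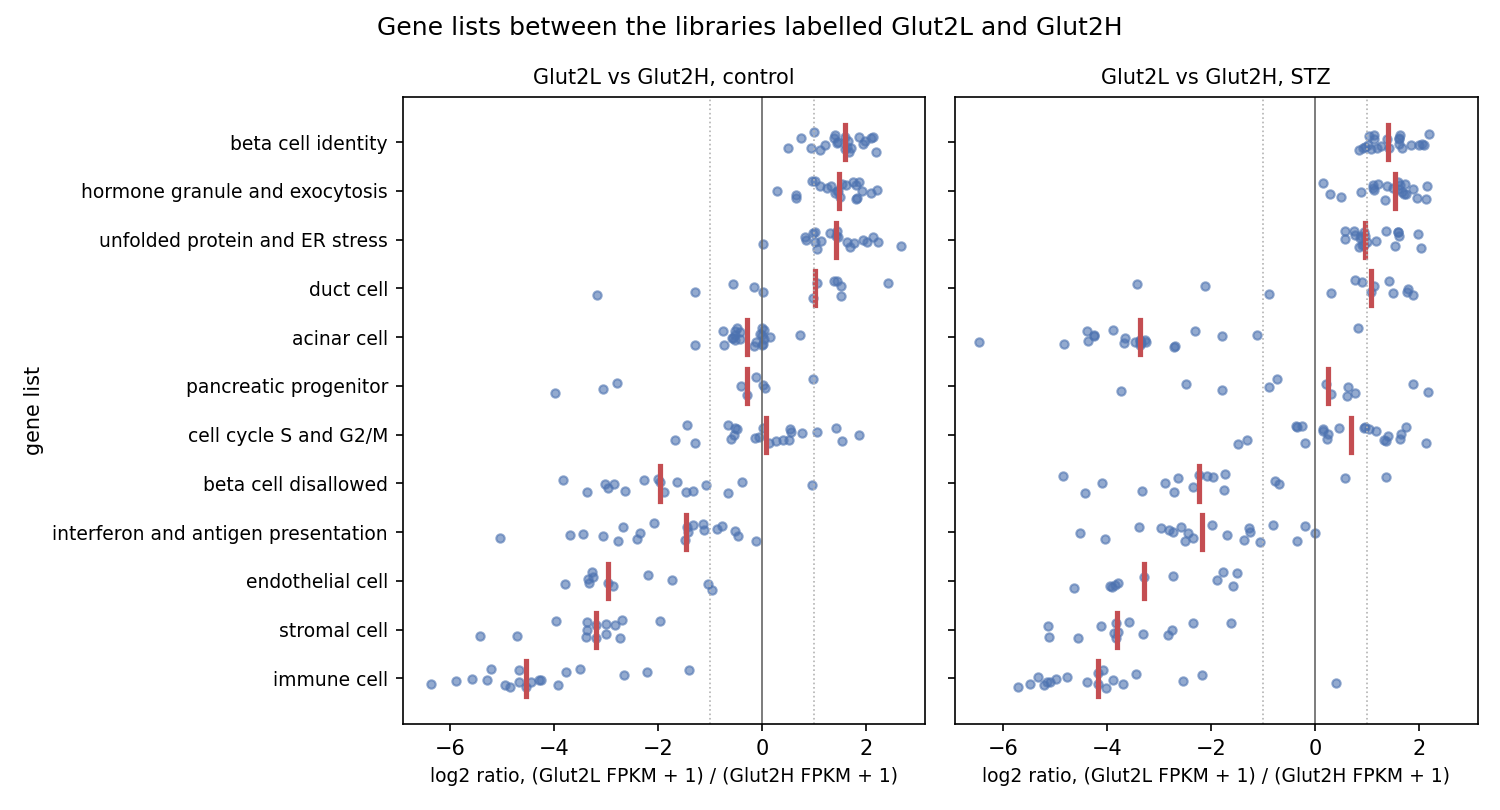
Log2 difference of each member of 12 gene lists between the library labelled Glut2L and that labelled Glut2H, in control mice (left) and after STZ (right). Each dot is a gene, the red bar is the list median and dotted lines mark 2-fold; the immune medians were -4.55 and -4.16, the beta cell medians 1.59 and 1.41, and the acinar medians -0.30 and -3.36, the control acinar and progenitor medians changing sign when rescaled to an equal sum over all rows.

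Over all genes, 3203 of 16234 were at least 2-fold higher and 3002 at least 2-fold lower in the library labelled Glut2L in control mice, and 3634 and 2814 of 15839 after STZ. Among protein-coding genes without selenoproteins, a set chosen after the values were seen, the counts were 2277 and 2204 of 13239, and 2552 and 2153 of 13052. Of the 12394 such genes measured in both pairs, 923 were higher and 1301 lower in both, where independence of the pairs gives 380.5 and 310.1. The lowest protein-coding genes, ranked after the values were seen, included several leukocyte genes. In control mice they were led by Retnla, at 173 FPKM and listed at 0 in the library labelled Glut2L, then Cd52 and the chemokine gene Ccl3, at 72.4 and likewise listed at 0; Arhgap27 (132 and 1.10), H2-Ab1 and Il1rn (392 and 5.62) followed. After STZ they were led by Ms4a4c (175 and 0.105), Retnla (465 and 2.59) and the colipase gene Clps (506 and 4.75). The highest in control mice were Tmsb15b2 (4.10 and 251) and Kctd15 (1.01 and 76.6), with Tph2, an enzyme of serotonin synthesis, at 0.808 and 23.2, and after STZ Hist1h2an (0 and 31.6) and Kbtbd4 (0.349 and 32.9). The higher share of the calls was 51.6% in control mice and 56.4% after STZ, but 80.2% and 86.9% when rescaled to an equal sum over all rows, which moved the median of all genes from 0.15 and 0.23 to 0.81 and 1.08, and 43.0% and 43.1% with that median set to 0. With the further condition that the deposited intervals do not overlap, 83 and 681 genes were left in control mice and 154 and 658 after STZ.

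The comparison of STZ with control within each gate asks how the toxin altered the cells of each gate, and, from the series title, whether diabetes raised the proliferation of progenitors. In the library labelled Glut2L, most acinar genes were at least 2-fold lower after STZ and the p53 and DNA damage list had a median above 0, while no beta cell identity gene differed at least 2-fold. Of 21 acinar genes, 20 were at least 2-fold lower after STZ (median -2.70, percentile 0). Clps (ENSMUSG00000024225, chromosome 17, 28558149 to 28560766) was at 540.2 and 4.75 FPKM in the control and STZ libraries, Zg16, a zymogen granule gene, at 201 and 8.03, Ctrl at 132 and 5.03, Cel at 147 and 7.03 and Pnlip at 329 and 22.7. Bhlha15, at 6.94 and 7.56, was the measured member that was not at least 2-fold lower. In the Glut2H libraries acinar genes gave a median of 0.01 (percentile 64.6), with 2 of 23 at least 2-fold higher and 1 lower, the sign turning when rescaled to an equal sum over all rows; Clps was at 487 and 506 and Try5 at 65.1 and 148. Differences between the gates in their STZ effects, here and for the groups that follow, were not tested.

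Of the 24 p53 and DNA damage genes, 4 were at least 2-fold higher after STZ in the library labelled Glut2L and 0 lower (median 0.54, percentile 100). The 4 were the death receptor gene Fas (ENSMUSG00000024778, chromosome 19, 34290666 to 34327772) at 1.31 and 8.63 FPKM, Ccng1 at 33.8 and 94.6, Pmaip1, which encodes the BH3-only protein Noxa, at 0.643 and 2.64, and Plk2 at 11.5 and 26.6. Below 2-fold, Aen was at 37.2 and 72.5, Bax at 44.2 and 81.7, the p21 gene Cdkn1a at 37.7 and 68.6 and Mdm2 at 49.2 and 82.0. In the library labelled Glut2H the median was -0.05 (percentile 45.7), which turned to 0.02 with the median of all genes set to 0. There Fas, at 4.70 and 0.137, Bbc3, which encodes Puma, at 10.9 and 2.25, and Rrm2b, a p53-induced ribonucleotide reductase subunit, at 8.52 and 3.47, were at least 2-fold lower after STZ, and Cdkn1a was at 29.9 and 43.8.

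Beta cell identity genes had 0 of 22 members at least 2-fold higher or lower after STZ in the libraries labelled Glut2H and 0 of 22 in those labelled Glut2L. Their medians were 0.14 and 0.03, and the granule medians 0.02 and 0.00, the signs depending on the scaling. Ins2 was at 57345 and 52596 FPKM in control and STZ libraries labelled Glut2H and at 294540.0 and 175841 in those labelled Glut2L, and Slc2a2 at 8.74 and 10.8 in the former and at 41.0 and 33.7 in the latter. In the Glut2L libraries Ucn3, a marker of beta cell maturity, was at 33.5 and 20.1, G6pc2 at 420.0 and 247, Foxa2 at 12.8 and 24.2 and Trpm5 at 6.08 and 10.6. In the Glut2H libraries Foxa2 was at 6.23 and 12.3. Unfolded protein genes had a median of -0.35 in the Glut2L libraries (percentile 1.41), with Ddit3, the CHOP gene, at 345 and 180.1 and Sdf2l1 at 99.7 and 55.2. In the Glut2H libraries their median was 0.02, with a sign that depended on the scaling.

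Values with 4 entries are in the order Glut2H control, Glut2L control, Glut2H STZ and Glut2L STZ. Alpha cell genes had a median of 0.76 after STZ in the Glut2L libraries (percentile 99.3) and 0.27 in the Glut2H libraries (percentile 88). Gcg was at 2287, 4170.0, 4337 and 9893 FPKM, and Gc at 11.5, 13.2, 16.1 and 31.0. Sst, at 1702, 2366, 2157 and 2604, differed less. The delta, PP and epsilon medians were 0.11 in the Glut2H libraries, a sign that depended on the scaling, and 0.18 in the Glut2L libraries. Interferon and antigen presentation genes had medians below 0 after STZ in both gates, with 4 of 20 at least 2-fold lower and 0 higher in the Glut2H libraries (median -0.63, percentile 0) and 6 of 20 lower and 0 higher in the Glut2L libraries (median -0.74, percentile 0). Ifit3 was at 105, 11.6, 38.4 and 4.63, Psmb9 at 57.5, 12.8, 15.5 and 11.96, Gbp3 at 19.0, 6.12, 11.5 and 1.23 and Oas1a, which was not lower in the Glut2H libraries, at 6.32, 4.32, 6.38 and 0.454. Immune markers did not move with them. Their median in the Glut2H libraries was 0.09 (percentile 84.4), a sign that depended on the scaling. In the Glut2L libraries it was 0.36 (percentile 97.7). Endothelial markers were at least 2-fold lower for 3 of 12 and 3 of 8 (medians -0.55 and -0.91, percentiles 0.7 and 0.420); Flt1 was at 23.9, 1.46, 7.86 and 0.336 and Plvap at 60.3, 5.32, 26.5 and 0.795. Stromal markers had medians of -0.10 and -0.48 (percentiles 31.2 and 6.56), with Vim at 546, 33.7, 455 and 11.97.

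Progenitor genes had a median of 0.41 after STZ in the Glut2L libraries (percentile 94.9), where Lgr5, at 0.978 and 4.49 FPKM, was at least 2-fold higher, and -0.29 in the Glut2H libraries (percentile 26.0). In the latter Ptf1a, at 0.198 and 2.45, was at least 2-fold higher and Aldh1b1, at 22.3 and 2.29, lower. Cell cycle genes had medians of 0.40 in the Glut2L libraries (percentile 97.9) and -0.19 in the Glut2H libraries (percentile 39.4). In the Glut2L libraries Tpx2, at 1.82 and 7.27, and Cdc20, at 1.79 and 4.97, were at least 2-fold higher after STZ and Ccnb1, at 7.14 and 2.20, lower. In the Glut2H libraries Ccna2, at 0.496 and 2.33, was higher, Cdk1, at 1.68 and 0.156, was lower, and Bub1 and Ccnb2, at 2.10 and 1.25 in the control, were listed at 0 after STZ.

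**Figure D3:**
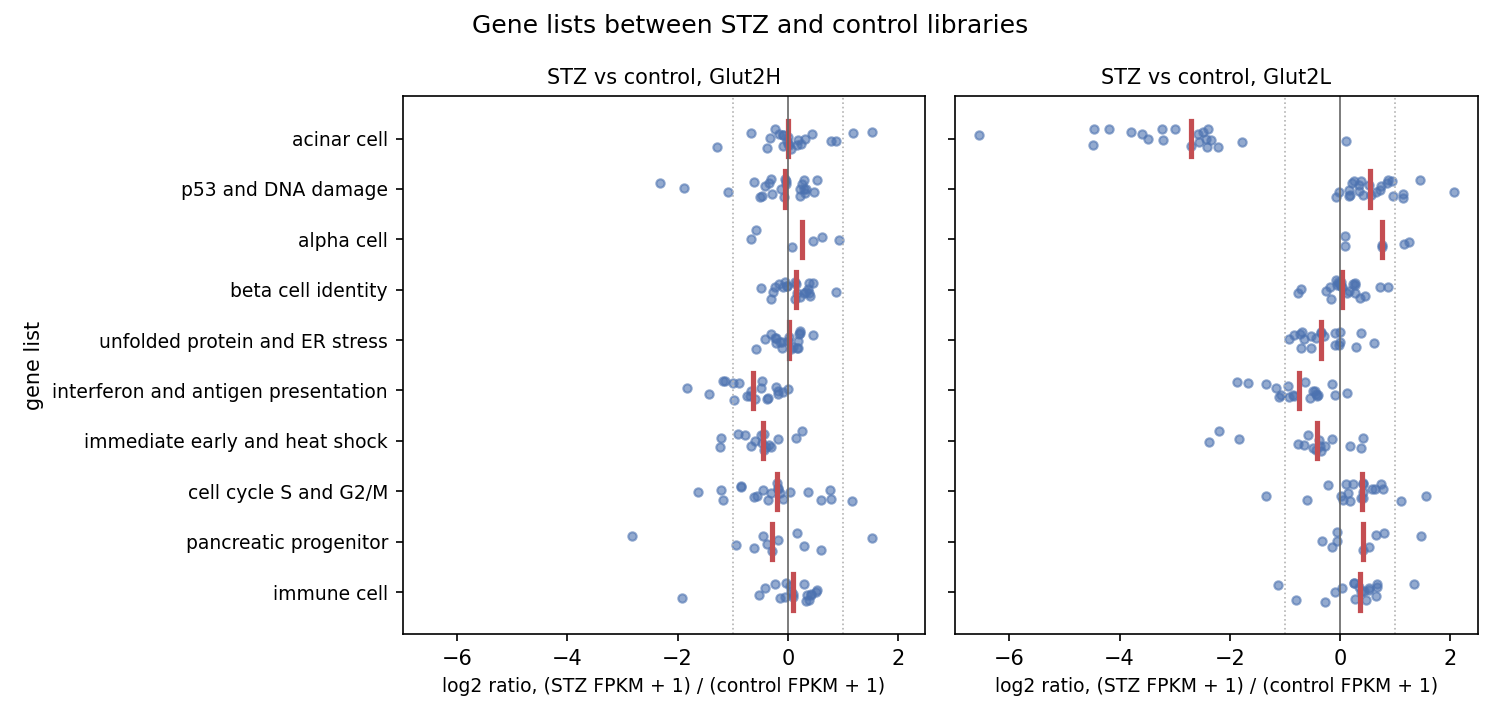
Log2 difference between STZ and control libraries of each member of 10 gene lists, in the libraries labelled Glut2H (left) and Glut2L (right). Each dot is a gene, the red bar is the list median and dotted lines mark 2-fold; the acinar medians were 0.01 and -2.70 and the p53 medians -0.05 and 0.54, both Glut2H medians changing sign with the scaling.

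Over all genes, 1496 of 15558 were at least 2-fold higher and 2153 at least 2-fold lower after STZ in the Glut2H libraries, and 1585 and 1726 of 15602 in the Glut2L libraries. Among protein-coding genes without selenoproteins the counts were 930 and 1283 of 12897, and 863 and 960 of 12640. Of 11640 such genes measured in both gates, 101 were higher and 144 lower in both, where independence gives 43.59 and 63.36. A similar number went in opposite directions: 108 were higher in the Glut2H and lower in the Glut2L libraries and 134 the reverse, where independence gives 47.62 and 58.01. In the Glut2H libraries the highest protein-coding genes after STZ were Tmsb15b2 (4.10 and 217), Eps8l1 (0.646 and 47.3) and RP23-395P6.9 (0 and 22.6), with Pklr, a pyruvate kinase gene, at 1.09 and 42.1. The lowest were Hba-a1 and Hbb-bs, both listed at 0 after STZ, and Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, at 169 and 6.30; the drug efflux gene Abcb1a was at 42.8 and 1.60. In the Glut2L libraries the highest were Sowahc (0.649 and 25.7), Tpmt (0 and 14.6) and Fam166a (1.38 and 35.2). Clps, Kctd15 (76.6 and 1.64), Zg16 and Ctrl were the lowest there, and Lars2 was at 41.2 and 1.74. With the further condition that the deposited intervals do not overlap, 59 and 102 genes were left in the Glut2H libraries and 50 and 64 in the Glut2L libraries. Rescaling to an equal sum over all rows gave 606 and 1315 in the Glut2H libraries and moved the median of all genes there from -0.07 to -0.23.

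The difference between the STZ effects of the gates asks whether cells with little Glut2 responded otherwise than cells with much. It was not tested, since each effect rests on 1 library against 1. The acinar list set the gates furthest apart among lists with a lower effect in Glut2L: 21 of 23 genes had an STZ effect at least 2-fold lower in the libraries labelled Glut2L (median -3.14, percentile 0), with Clps at -6.61 and Cel at -4.38 on the log2 scale. The p53 list went the other way, with 8 of 24 at least 2-fold higher in Glut2L (median 0.65, percentile 100). These were Fas at 4.39, Bbc3 at 2.05, Plk2 at 1.75, Pmaip1 at 1.65, Rrm2b at 1.44, Aen at 1.41, Eda2r at 1.36 and Ccng1 at 1.13. Of these, Fas, Bbc3 and Rrm2b were also at least 2-fold lower after STZ in the Glut2H libraries. Within the Glut2L libraries 4 of 24 p53 genes were at least 2-fold higher after STZ. Among progenitor genes (median 0.61, percentile 94.95) Aldh1b1 was at 3.26, Lgr5 at 1.501 and Ptf1a at -1.52. The Aldh1b1 value came mostly from its fall in the Glut2H libraries, from 22.3 to 2.29 FPKM. In the Glut2L libraries it stayed below 1 FPKM, at 0.470 and 0.985. Cell cycle genes had a median of 0.57 (percentile 95.1), with Bub1 at 2.41, Ccnb2 at 1.75, Cdc20 at 1.65, Cdk1 at 1.62, Mki67 at 1.08 and Ccna2 at -1.76. The Bub1 value came mostly from the Glut2H libraries, where it was at 2.10 and 0 FPKM, against 0.139 and 0.958 in the Glut2L libraries. Ccnb2 and Cdk1 were also lower after STZ in the Glut2H libraries. The alpha median was 0.67 (percentile 94.3), the endothelial median -0.53 (percentile 2.17) and the stromal median -0.49 (percentile 1.87). The red blood cell median of 3.96 over 4 genes came from hemoglobin in the Glut2H control library, and the beta cell median was -0.03, a sign that depended on the scaling. In all, 3257 of 17732 genes had an effect at least 2-fold higher in Glut2L and 2745 at least 2-fold lower, and 1972 and 1698 of 13896 protein-coding genes without selenoproteins. The protein-coding genes furthest apart were Tnfrsf4, at 5.78, and Lcp2, at 5.76, with higher effects in Glut2L, and Clps, Fam154b, at -6.41, and Tmsb15b2, at -6.20, with lower ones. Across protein-coding genes the 2 STZ effects had a correlation of r = 0.0185, against 0.628 for the gate differences of control and STZ mice, and genes are not independent replicates. Rescaling to an equal sum over all rows moved the median of all differences from 0.07 to 0.26.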

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

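Of the tests below, the spread over acinar genes was chosen only after the result was seen. In the results that follow the STZ effects of the gates differed in sign as deposited; none of these differences was tested, since each effect rests on 1 library against 1. The acinar list (medians 0.01 in Glut2H and -2.70 in Glut2L) had a median difference of STZ effects, Glut2L minus Glut2H, of -3.14 on the log2 scale, and the p53 and DNA damage list (medians -0.05 and 0.54) one of 0.65. Both differences lay outside the central 95% of random lists, but both Glut2H medians are near 0 and their sign depends on the scaling, so no direction in Glut2H is drawn from them. Among protein-coding genes without selenoproteins and with at least 5 FPKM in some library, 168 were at least 2-fold higher after STZ in one gate and at least 2-fold lower in the other, 94 of them higher in the libraries labelled Glut2L and 74 lower there. In the wider set of 11640 such genes measured in both gates, opposite calls (108 and 134) were about as common as calls in the same direction (101 and 144). The 5 largest differences in each direction among the 168 are given. Tnfrsf4 differed by 5.78, Lcp2 by 5.76, Mpped2 by 5.50, Hist1h2an by 5.22 and Med10 by 5.13. Fam154b differed by -6.41, Engase by -5.42, the hexokinase gene Hk1 by -5.37, Notch4 by -4.71 and Phpt1 by -4.59. For Hk1 the FPKM were 13.8, 27.6, 97.7 and 3.62, and for Notch4 6.43, 9.59, 19.8 and 0.133.

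Acinar genes were at least 2-fold lower after STZ for 20 of 21 measured genes in the library labelled Glut2L and for 1 of 23 in that labelled Glut2H. Library scaling is argued against, since a common factor shifts all genes and the median of all genes in the Glut2L comparison was 0.004. Over the 3 rescalings the highest Glut2L acinar median was -2.61. These rescalings treated the control and STZ libraries of Glut2L nearly alike (factors 0.604 and 0.640 over all rows), so they could hardly have moved it. RNA from a single acinar source, present in less amount in the Glut2L library after STZ, may explain the pattern, and the sort for insulin-positive cells should have removed such cells; its most abundant genes in the Glut2L control, Ctrb1 at 801 FPKM and Clps at 540.2, were at 158 and 4.75 after STZ, and 1 of the 24 genes of the list is in another list. A single source would lower its transcripts by a common factor. The SD of the STZ effect over 18 acinar genes with at least 50 FPKM in the control was 1.10. For the same genes it was 0.42 in Glut2H and 0.30 between the control gates, where their medians were 0.02 and -0.30. Acinar levels were higher in those libraries than in the Glut2L STZ library, so these 2 values cannot decide on a single source. At the lower levels of the Glut2L STZ library random lists had a median SD of 0.77 (percentile 74.3). These lists drew from all rows, noncoding ones included, and lists of protein-coding genes alone were not drawn. The SD of the STZ effect in Glut2L was 1.31 over all rows and 0.758 over protein-coding genes without selenoproteins. The random lists may therefore overstate the spread to set beside acinar genes, and this source and a change in the cells were not told apart. An effect of STZ on the cells of the low gate stays open and was not tested.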

How the results depend on the processing

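Protein-coding genes without selenoproteins were an alternative chosen after the data were seen; the others were planned. Counts are given as higher and lower, in the order control gates, STZ gates, STZ in Glut2H, STZ in Glut2L and difference of STZ effects, and those named here left the range of 1.5 times the reported count. All 10 counts stayed within it with a pseudocount of 0.1, without a filter, with the median set to 0, without dominant rows and from the per-sample tables. With a pseudocount of 5 they were 1418 and 1462, 1471 and 1443, 570 and 671, 537 and 598, and 1248 and 1197, since a larger pseudocount shrinks ratios of low values. A filter of 5 FPKM, which tests fewer genes, gave 1937 lower in the control gates, then 2335 and 1863, 910 and 1114, 857 and 926, and 1879 and 1731. Rescaling to an equal sum over all rows gave 5622 and 1384, 7464 and 1126, 606 and 1315, and 1523 lower for the difference; Gm20594 alone took 61.0% and 68.5% of the Glut2H sums, and the cause was not tested further. Named genes alone, a smaller set, gave 892 and 1268 for STZ in Glut2H, 824 and 931 in Glut2L, and 1925 and 1642 for the difference. Protein-coding genes without selenoproteins, also a smaller set, gave 930 and 1283, 863 and 960, and 1972 and 1698. Requiring deposited intervals that do not overlap, a stricter condition, left 83 and 681, 154 and 658, 59 and 102, and 50 and 64; the difference of STZ effects has no such interval and was not run. Of the list medians of at least 1 in size and the named genes at 2-fold or more, 1 changed sign under an alternative: the Notch pathway median between the STZ gates was -1.16 and became 0.23 when rescaled to an equal sum over all rows, and the cause was not tested. A further 39 of 118 list medians, all below 1 in size, changed sign under at least 1 of the 3 scalings, among them both oxidative stress gate medians. Under that rescaling 41 further list medians and 338 of 678 named gene values moved without such a reversal; under the other scalings at most 5 medians and 159 gene values did. A pseudocount of 5 moved 14 medians and 298 gene values, and one of 0.1 moved 11 and 237. The read number is unknown, so no limit from depth can be given; intervals with a median half-width of about 80.3% of the FPKM in the Glut2L control library left few genes apart.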

Other observations

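Of the tests below, those on the cells among the Glut2H libraries, on a lower share of beta cells and on exchanged labels were chosen only after the result was seen. G1 cyclins and CDK inhibitors had gate medians of 0.37 in control mice and 0.14 after STZ (percentiles 74.1 and 36.2), the STZ median turning to -0.10 with the median of all genes set to 0. Ccne2, which encodes cyclin E2, stood at 5.42, 23.0, 3.03 and 26.6 FPKM and Ccnd2, the cyclin D of beta cells, at 29.8, 75.6, 27.1 and 67.9. After STZ the list had a median of 0.31 in the Glut2L libraries (percentile 98.2) and 0.00 in the Glut2H libraries. The 2-fold counts went the other way. In the Glut2L libraries 0 of 12 were at least 2-fold higher and 1 lower, and in the Glut2H libraries 3 of 14 were higher and 0 lower. The retinoblastoma gene Rb1 was at 15.1, 18.4, 52.96 and 35.4. Immediate early and heat shock genes had gate medians of 0.38 and 0.33 (percentiles 63.0 and 62.5) and STZ medians of -0.45 in the Glut2H and -0.42 in the Glut2L libraries (percentiles 0.310 and 0.690), where 2 and 3 of 16 were at least 2-fold lower after STZ and 0 higher. Hspb1 was at 9.48, 51.8, 6.82 and 9.21, Hspa1b at 29.3, 115, 15.3 and 24.2 and Hspa1a at 10.4, 53.3, 3.92 and 14.2, while Zfp36 was at 153, 41.0, 101 and 31.5 and Ier3 at 127, 50.5, 92.2 and 33.5; between the gates 5 of 16 were at least 2-fold higher and 2 lower in the library labelled Glut2L in control mice, and 4 and 2 after STZ. Notch pathway genes had gate medians of -0.30 and -1.16 (percentiles 13.9 and 0.280), both positive when rescaled to an equal sum over all rows, with Notch1 at 17.3, 82.4, 28.7 and 5.87, Jag1 at 18.4, 3.72, 21.6 and 2.62 and Dll1 at 1.33, 6.51, 1.40 and 7.43. Their STZ medians were -0.01 and 0.13 in the Glut2H and Glut2L libraries, the Glut2H sign depending on the scaling.

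Oxidative stress and metallothionein genes had gate medians of -0.43 and -0.39 (percentiles 0.520 and 1.20), both positive when rescaled to an equal sum over all rows. The catalase gene Cat, at 40.4, 3.64, 65.7 and 9.42 FPKM, and Prdx1, at 1139, 261, 1357 and 314, were lower in the libraries labelled Glut2L, and Txnip, at 215, 626, 262 and 707, was higher. The metallothionein genes stood at 975.1, 862, 891 and 327 for Mt1 and 1131, 725, 761 and 266 for Mt2, and the list's STZ medians were 0.10 in the Glut2H libraries, a sign that depended on the scaling, and 0.11 in the Glut2L libraries. Glycolysis genes had gate medians of 0.28 and -0.10 (percentiles 52.5 and 12.03), the STZ one turning to 1.03 when rescaled to an equal sum over all rows, and STZ medians of 0.06, with a sign that depended on the scaling, and -0.33. Between the gates 1 of 14 was at least 2-fold higher and 2 lower in the library labelled Glut2L in control mice, and 1 and 3 of 14 after STZ, with Pfkm at 2.54, 10.2, 1.97 and 6.32, Hk2 at 14.9, 0.119, 14.4 and 0.545, Ldha at 83.6, 16.5, 80.6 and 10.2 and Hk1 at 13.8, 27.6, 97.7 and 3.62. Nuclear-encoded respiratory chain genes had gate medians of 0.61 and 0.34 (percentiles 90.9 and 65.9), with Ndufs3 at 19.0, 66.6, 25.3 and 61.0, Ndufv1 at 19.6, 76.4, 30.9 and 39.5 and Ndufv2, lower in both libraries labelled Glut2L, at 33.4, 26.3, 48.9 and 20.6, and STZ medians of 0.05, again depending on the scaling, and -0.13. Neural and glial genes had gate medians of 0.15, which turned to -0.05 without the dominant rows, and 0.74 (percentiles 53.8 and 89.8), with 5 of 11 at least 2-fold higher and 3 lower in the library labelled Glut2L in control mice and 2 and 1 of 9 after STZ; Tubb3 was at 4.48, 16.4, 6.35 and 10.6 and Nes at 28.4, 2.52, 25.2 and 3.70. After STZ the duct medians were -0.20 and 0.15 in the Glut2H and Glut2L libraries, the Glut2L sign depending on the scaling, the disallowed medians -0.22 and -0.63, and the dedifferentiation medians -0.36 and 0.02, the last with a sign that depended on the scaling.

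In the libraries labelled Glut2H, Slc2a2 and beta cell genes were lower and immune, endothelial and stromal genes higher than in those labelled Glut2L. Library scaling is argued against, since Slc2a2 stayed higher in Glut2L by at least 1.32 on the log2 scale over 3 rescalings and both pairs, and the immune median stayed at -2.93 or lower. In the control pair, acinar and immune medians 4.26 apart (larger SD of members 1.24) argue against a lower share of beta cells alone. This holds only if the acinar RNA came from the sorted cells, which was not tested. After STZ the medians were 0.80 apart (SD 1.45), within that spread, so the STZ pair does not argue against it. Immune, endothelial and stromal cells among the cells of the Glut2H libraries stay open as a candidate explanation, although the sort for insulin-positive cells should have removed them. At least 90.9% of the measured members of each of these 3 lists were at least 2-fold higher there in both pairs. Cd74 was at 1027 and 1305 FPKM and Vim at 546 and 455 in the Glut2H control and STZ libraries. Of the 21, 12 and 14 genes of the lists, 0, 0 and 1 are in another list. Markers of such cells were thus higher there, but this share restates the pattern and cannot by itself decide whether such cells were present. Whether the gate labels were exchanged cannot be told apart from this, as Slc2a2 exceeded the beta cell median by 0.52 in control mice and by 0.14 after STZ and the gate is on protein; a difference between cells of the gates was not tested and stays open.

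Some genes with an annotated selenocysteine had very high FPKM, and several differed widely between libraries: Msrb1 was at 1132, 29498, 1369 and 285, Sepp1 at 5054, 21641, 4271 and 6882 and Gpx1 at 0, 60.1, 20.6 and 3.29, and 6 of 20 exceeded 1000 FPKM in a library against 44 of 13896 other protein-coding genes. Their mean SD over the 4 libraries was 1.13 on the log2 scale, at percentile 98.8 of random lists (median 0.66), which restates the differences and does not say what made them. An effect of how these gene models are quantified and joint regulation by gate or STZ therefore cannot be told apart: the highest share that went the same way was 100%, with 0 higher and 5 lower after STZ in Glut2L, but 3 higher and 4 lower in Glut2H, and 10 and 3, then 7 and 3, between the gates in control and STZ mice.

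All 37 rows on the mitochondrial chromosome and all 255 rows on scaffolds and patches were listed at 0 in every library, while 22945 of 38878 rows on numbered and sex chromosomes were above 0 in at least 1 library. Rn7sk, a small nuclear RNA gene, had the highest FPKM in both libraries labelled Glut2L, and the 20 highest rows took 82.3%, 65.6%, 84.0% and 65.1% of the summed FPKM. Across 17732 genes the log2 values of the libraries had correlations of 0.722 between the control gates, 0.721 between the STZ gates, 0.822 between treatments in Glut2H and 0.823 in Glut2L, and genes are not independent replicates.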
